A study of Mus musculus with 6 samples.

How the data were processed

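RNA was measured by sequencing in hypothalamus tissue from 6 mice, 3 aged 22 months (aged) and 3 aged 12 weeks (young). Per the labels' design text, each age group held 5 mice in a behavioural experiment, and 3 of each were drawn at random for sequencing. The labels give no sex, litter, batch or day. Per the labels' protocols, total RNA was extracted with the mirVana kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand.

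The deposited count table holds whole-number read counts per gene for 18228 genes, with no normalization by the authors. The deposited FPKM table holds the same genes as FPKM, read counts scaled to gene length and library total. FPKM equals the counts divided by a gene length and the library's total count, within a relative tolerance of 1e-06, for 18228 of 18228 genes, so both tables carry the same reads. Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq, and the build GRCm39, are named in the submitters' processing notes without versions. The annotation release, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Reads from near-identical genes (Hspa1a and Hspa1b, C4b and its paralog, the H2 genes, ribosomal protein genes and their pseudogenes) and from overlapping genes could have been divided or dropped at that step, and values for these genes are uncertain to that extent. Mitochondrially encoded genes and Xist are not analysed here. Chromosomes were taken by gene symbol from a GRCm38 annotation for 18116 of 18228 genes (99.4%), only to class genes as autosomal, X-linked or Y-linked; no coordinates are given because the builds differ.

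The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, aged against young, with no covariate. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 14702 genes with 99.9% of all counts. Libraries were scaled with TMM factors. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 of aged over young with the standard error (SE) implied by the test, and levels are TMM-normalised CPM, reads relative to the scaled library total. The biological coefficient of variation was 8.52%. Each library is from a separate mouse and was counted as 1 sample. As a check for a library deposited more than once, replicates were compared with sampling noise (chi-square per degree of freedom 4.04 to 12.1, where copies would give 1 or less).

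Before the data were examined, 52 gene lists, the rule for named genes, the tests and the processing alternatives were fixed. The lists cover cell types, neighbouring brain regions and tissues, hypothalamic signalling, immune, stress and metabolic pathways. A list was tested with 3 or more tested members and without the sex-linked list, which left 49. The list test was limma's camera (limma 3.58.1) with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The count of members adjusted over the list alone is given beside that over all genes. The naming rule took the 12 largest changes in each direction among passing genes whose groups did not overlap and whose mean log2 CPM was at least 1. It skipped gene models named only by an identifier. It also took up to 4 members per list with the smallest adjusted p, passing or not, and the Y-linked genes as a check of sex. Genes outside the rule are said to be so where they are named, and a few genes that the rule takes are not reported here.

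Alternatives were other scalings, other low-count filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), robust estimation, other thresholds, the replicate number as a block and leaving out each library in turn. After the data were seen, 2 were added: leaving X- and Y-linked genes out of the counts, and removing per library the loess trend of log counts on gene length. Gene length was recovered from the counts and FPKM. On simulated data with the means and spread of these 14702 genes, edgeR recovered 70.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 6.52% false calls, and made 2 calls where no gene was changed. In the same simulation, a list raised 1.2-fold had a camera adjusted p of 7.54e-17 with the preset correlation and 0.0754 with an estimated one. Genes were drawn independently there, while estimated correlations within the real lists ran from -0.109 (perivascular macrophages) to 0.803 (T cells). The simulation therefore does not show which camera run suits the real lists. Medians of small marker lists have bootstrap intervals from 10000 resamples of their genes. These intervals take genes as independent and show the spread among genes, not between mice.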

Results

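Hypothalamus RNA was sequenced from 3 aged mice (22 months) and 3 young mice (12 weeks), to find genes that accompany cognitive decline with age in this brain region. Each library held between 17208291 and 18884403 counted reads. Aged libraries averaged 17966395 ± 849420 and young libraries 17666904 ± 293425 reads (SD, n = 3 each), a difference within the spread (two-sided exact permutation p = 0.8; the smallest p that 20 assignments allow is 0.1). Correlations of log2 CPM across genes were 0.990 to 0.995 within an age group and 0.982 to 0.988 between groups. The first principal component, with 51.3% of the variance, separated the ages.

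Of 14702 genes tested, 474 were higher and 535 lower in aged hypothalamus. Of these, 111 rose and 40 fell by at least 2-fold; on log2(FPKM + 1) these were 50 and 2, and without single libraries 56 to 141 rose and 10 to 65 fell. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y led the higher genes. Ddx3y stood at 73.1 ± 0.915 CPM in aged and 0.590 ± 0.132 CPM in young libraries (SD, n = 3 each; edgeR adjusted p = 2.49e-09). Together these 4 genes had 3394 to 3617 reads in each aged library and 24 to 32 in each young library. The labels give no sex, and Y-linked expression divided the 6 libraries exactly as age did, so every difference below is between groups that differ in both. Of the other genes with the largest increases, Hspa1b, Tmem252, Atf3, Depp1, Maff, Plaur, Hspa1a and Nxf3 rose by 2.82 to 3.95 on the log2 scale. The largest decreases were in Slc6a3, the dopamine transporter (log2 fold change -2.63 ± 0.58 SE), Neurod6 (-2.11 ± 0.54), Tnfsf10 (-1.93 ± 0.43) and Chrna6, a nicotinic receptor subunit (-1.83 ± 0.41), with edgeR adjusted p of 0.0301, 0.0472, 0.0312 and 0.0308; they lost the call in 9, 10, 5 and 9 of 20 alternatives. Fzd10, Grid2ip, Col3a1, Clec2d, Hes5, Npvf, Synpo2 and Ndnf followed, at -1.70 to -1.30.

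The groups did not overlap in 1008 of the 1009 called genes; over all tested genes the share without overlap was 31.7%, against 10% by chance. Unadjusted p fell under 0.05 for 3859 genes, where 735 are expected by chance. Scaling by total counts alone gave 627 higher and 446 lower, and limma-trend on log2(FPKM + 1) gave 616 and 293. The total of 1009 depended on single libraries: it was 244 without aged replicate 1, 1633 without aged replicate 2, 150 without aged replicate 3, and 262, 579 and 396 without young replicates 1, 2 and 3.

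Genes that respond to glucocorticoids were higher in aged hypothalamus. Of 18 measured members, 11 rose, 0 fell and 7 did not pass (13 rose when adjusted over the list alone). Sgk1, a kinase induced by serum and glucocorticoids, rose from 30.8 ± 3.77 to 148 ± 39.3 CPM (SD, n = 3 each; log2 fold change 2.26 ± 0.19 SE, edgeR adjusted p = 0.000508). Map3k6 rose by 2.37 ± 0.24, Cdkn1a, a cell cycle inhibitor, by 1.68 ± 0.21 and Per1, a clock gene, by 0.97 ± 0.10 on the log2 scale. The list's camera adjusted p was 4.21e-22, and adjusted p = 0.163 with an estimated correlation.

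Of 20 immediate early genes, 8 rose and 12 did not pass (10 rose when adjusted over the list alone). Nr4a3 and Nr4a1, orphan nuclear receptors, rose by 2.73 ± 0.34 and 1.30 ± 0.18, and the transcription factors Fosl2 and Fosb by 2.34 ± 0.28 and 1.70 ± 0.18. Of 19 cytosolic heat shock genes, 9 rose and 10 did not pass (15 rose when adjusted over the list alone). Hspa1b rose from 5.90 ± 1.21 to 91.5 ± 65.7 CPM (SD, n = 3 each; edgeR adjusted p = 0.00719) and Hspb1 from 4.62 ± 0.385 to 19.6 ± 8.74 CPM (edgeR adjusted p = 0.00844). Camera adjusted p was 1.66e-12 for the early genes and 1.87e-13 for the heat shock genes; these became adjusted p = 0.249 and adjusted p = 0.295 with an estimated correlation. Of 24 endoplasmic reticulum stress genes, 6 rose and 18 did not pass (10 rose and 1 fell when adjusted over the list alone). They included Atf3 (3.75 ± 0.30), Creld2 (0.64 ± 0.12), Ppp1r15a (0.63 ± 0.12) and the chaperone Hspa5 (0.45 ± 0.09). Camera gave an adjusted p of 0.000117, and adjusted p = 0.295 with an estimated correlation. In the circadian clock list, Per1, Per2 and Cry1 rose, Nr1d1 fell and 14 of 18 did not pass (6 rose and 2 fell when adjusted over the list alone). Its camera adjusted p was 0.0282, and adjusted p = 0.339 with an estimated correlation. Aged replicate 2 had the lowest level of the 3 aged libraries for Hspa1b (27.5 CPM, against 88.4 and 159) and Sgk1 (104 CPM, against 181 and 158).

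**Figure D1:**
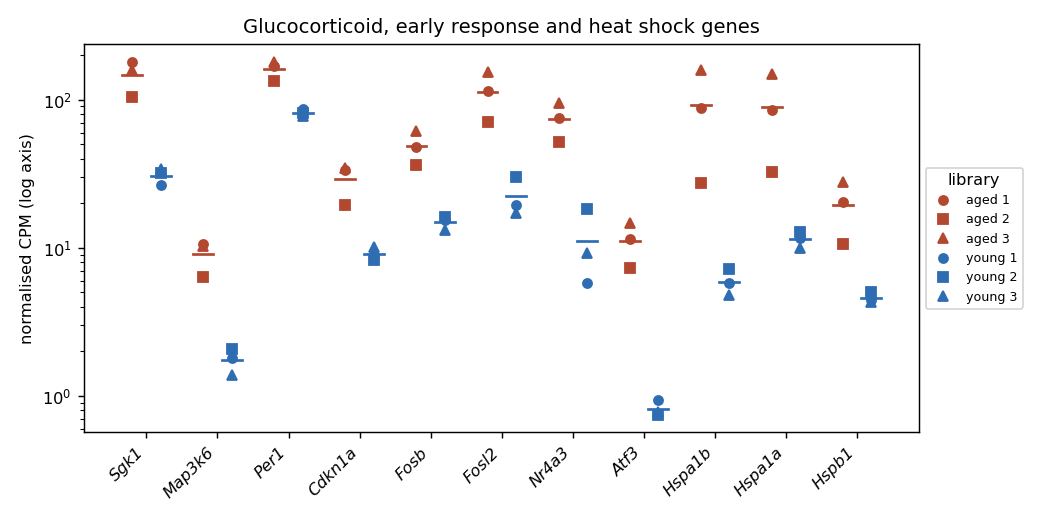
Levels of 11 glucocorticoid, early response and heat shock genes in each library, as normalised CPM on a log axis; symbols are libraries, and bars are group means. All 3 aged libraries lie above all 3 young libraries for each gene, and Hspa1b has the means 91.5 and 5.90 CPM.

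Some complement and microglial genes were also higher. Of 18 complement genes, 7 rose, 1 fell and 10 did not pass (9 rose and 1 fell when adjusted over the list alone). C4b rose from 55.8 ± 5.13 to 134 ± 20.7 CPM (SD, n = 3 each; log2 fold change 1.26 ± 0.12 SE, edgeR adjusted p = 0.000931). C3 rose from 4.56 ± 0.880 to 10.5 ± 1.43 CPM (SD, n = 3 each). On the log2 scale, C1qb and C1qa, parts of the complex that starts the classical pathway, rose by 0.65 ± 0.07 and 0.63 ± 0.08. Cd59a, a membrane inhibitor of complement, fell by 0.46. Of 21 disease-associated microglia genes, 8 rose and 13 did not pass (10 rose when adjusted over the list alone), among them Lyz2 (1.40 ± 0.11), Clec7a (2.41 ± 0.30), Lgals3 (1.23 ± 0.19) and Ctsz (0.46 ± 0.07). Both lists had a camera adjusted p of 3.05e-09, and adjusted p = 0.121 with an estimated correlation for both.

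Homeostatic microglia genes moved in both directions: of 18, 5 rose, 2 fell and 11 did not pass (9 rose and 4 fell when adjusted over the list alone). C1qa and C1qb, which also stand in the complement list, were among the 5. Ctss, the protease cathepsin S, rose by 0.96 ± 0.07, while P2ry13 and P2ry12, purine receptors chosen after their values were seen, changed by -1.24 and -0.42. For this list camera gave an adjusted p of 0.00447, and adjusted p = 0.339 with an estimated correlation. Of 15 MHC class I genes, 6 rose (9 when adjusted over the list alone), including H2-K1 (0.85 ± 0.11) and H2-D1 (0.67 ± 0.08). Of 11 MHC class II genes, Ctss and H2-Ab1 rose (5 when adjusted over the list alone). Of 29 interferon response genes, 6 rose (12 rose and 1 fell when adjusted over the list alone), such as Ifit1 (0.83 ± 0.16) and Ifit3 (0.62 ± 0.12). Of 13 tested genes in the cytokine and chemokine list, which also holds adhesion and signalling genes, 3 rose (3 when adjusted over the list alone). These were Ccl2 (3.28 ± 0.45), Icam1 (1.02 ± 0.25, lost in 10 of 20 alternatives) and Nfkbia (0.69 ± 0.10), of which only Ccl2 is a chemokine. Camera adjusted p for these 4 lists was 5.65e-09, 2.71e-06, 6.46e-05 and 0.00166, and adjusted p = 0.295, 0.163, 0.295 and 0.295 with an estimated correlation. Of 17 senescence genes, 4 rose, among them Cdkn1a, Ccl2 and Plaur (6 when adjusted over the list alone). Cdkn1a also stands in the glucocorticoid list and Ccl2 in the cytokine list. Nfkbia of the cytokine list stands in the glucocorticoid list too. The senescence list had a camera adjusted p of 0.00132, and adjusted p = 0.163 with an estimated correlation.

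**Figure D2:**
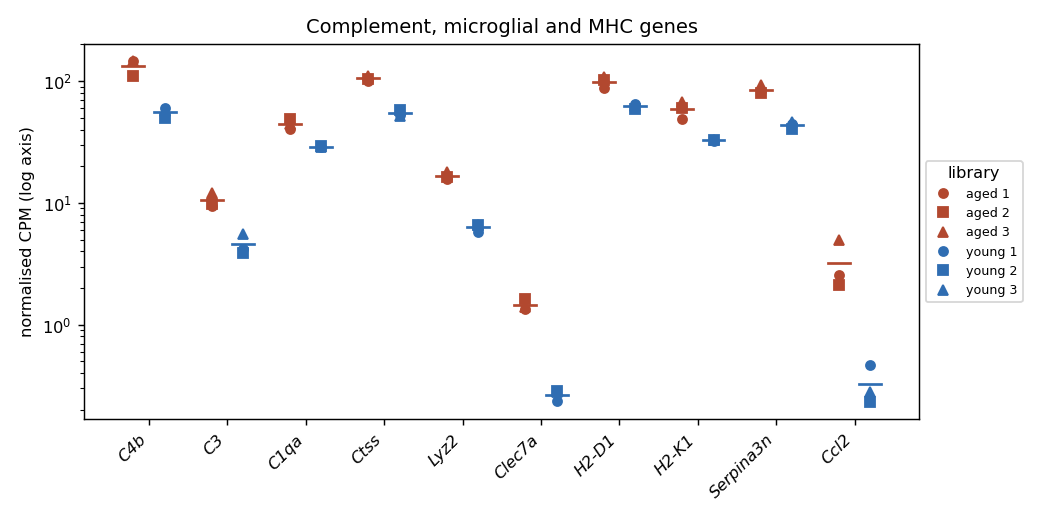
Levels of 10 complement, microglial, MHC, astrocyte and chemokine genes in each library, as normalised CPM on a log axis; symbols are libraries, and bars are group means. All 3 aged libraries lie above all 3 young libraries for each gene, and C4b has the means 134 and 55.8 CPM.

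Of 16 reactive astrocyte genes, 7 rose and 9 did not pass (8 rose when adjusted over the list alone). The 7 included Serpina3n (0.95 ± 0.08) and Vim (0.55 ± 0.08). They also included C4b, which stands in the complement list, and Hspb1, which stands in the heat shock list, so the counts share these genes. Of 16 general astrocyte markers, 5 fell and 11 did not pass (7 fell when adjusted over the list alone). Aqp4, the water channel of astrocyte endfeet, went from 161 ± 11.1 to 99.0 ± 16.4 CPM (SD, n = 3 each; edgeR adjusted p = 0.0102), and the transcription factor Sox9 fell by 0.83. Camera adjusted p was 1.40e-09 for the reactive and 2.46e-06 for the general markers, and adjusted p = 0.163 and 0.339 with an estimated correlation.

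Some genes of the oligodendrocyte lineage before myelination were lower. Of 15 precursor genes, 3 fell (5 when adjusted over the list alone), and of 13 newly formed oligodendrocyte genes, 5 fell (8 when adjusted over the list alone; 2 with the gene length trend removed, which is described below). Gpr17, a receptor of differentiating precursors, went from 88.7 ± 3.23 to 42.5 ± 9.69 CPM (SD, n = 3 each, edgeR adjusted p = 0.00546), and Neu4 fell by 0.71 and Tnr by 0.51. Gpr17 and Neu4 stand in both lists, so the counts for the lists share these genes. Tcf7l2, among the 5 newly formed oligodendrocyte genes that fell, also stands in the thalamus list. These lists had camera adjusted p of 8.64e-06 and 1.06e-05, and adjusted p = 0.295 and 0.163 with an estimated correlation. Among 18 myelinating oligodendrocyte genes, Hapln2 rose and Opalin fell (calls lost in 4 and 11 of 20 alternatives; 1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.606).

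Some vessel wall and matrix genes were lower. Of 14 pericyte and smooth muscle genes, 4 fell (8 when adjusted over the list alone), including the receptor Pdgfrb (-0.88 ± 0.12) and Vtn (-0.53 ± 0.08). Of 16 fibroblast and meningeal genes, 6 fell (8 when adjusted over the list alone), and of 28 extracellular matrix genes, 5 fell (8 fell and 3 rose when adjusted over the list alone). Col3a1 and Col1a1, fibrillar collagens, changed by -1.61 ± 0.24 and -0.99 ± 0.17, and the matrix protease Mmp14 by -0.95 ± 0.08 (edgeR adjusted p = 0.000503). Camera adjusted p for the 3 lists was 3.05e-06, 6.34e-06 and 0.00166, and adjusted p = 0.295, 0.163 and 0.301 with an estimated correlation; for matrix genes it was 0.0519 with fry. Of 16 endothelial genes, the glucose transporter Slc2a1 rose and Cldn5, Tek and Kdr fell (1 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.0959, and 0.0128 and 0.0137 without aged and young replicate 2).

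Some synaptic genes were lower by small amounts. Of 31 glutamate receptor and synapse genes, 5 fell (11 fell and 1 rose when adjusted over the list alone), including the receptor subunits Grin2b (-0.62 ± 0.13) and Grin3a (-0.38 ± 0.06). Of 25 synaptic vesicle genes, 4 fell (7 when adjusted over the list alone), among them Syn1, Rims1 and Bsn, by 0.42 to 0.47. Both passed camera, at adjusted p of 1.19e-05 and 2.45e-05, and adjusted p = 0.295 for both with an estimated correlation. Of 21 GABA signalling genes, Gabra5 rose and Gabbr2 and Gabrb1 fell (2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.0663). Longer genes were lower in aged libraries as a whole, with a median log2 fold change of 0.11 in the shortest of 10 equal classes and -0.12 in the longest. With that trend removed, 3 glutamate and 3 vesicle genes fell, and 412 genes were higher and 346 lower overall.

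Cytosolic ribosomal protein genes were the largest group to rise by count. Of 50, 27 rose and 23 did not pass (36 rose when adjusted over the list alone), such as Rps14 (0.56 ± 0.08), Rps12 (0.45 ± 0.06) and Rplp1 (0.45 ± 0.06). These genes are short, and 14 rose with the length trend removed. Of 45 nuclear oxidative phosphorylation genes, Ndufb8 and Ndufa1 rose (2 when adjusted over the list alone), and of 29 proteasome genes, Psmb6, Psmb1 and Psmc6 rose (5 when adjusted over the list alone). With the length trend removed, 0 proteasome genes rose, and 1 oxidative phosphorylation gene rose and 1 fell. Camera adjusted p was 4.21e-22, 8.48e-05 and 7.30e-05 for the 3 lists, and adjusted p = 0.295, 0.424 and 0.339 with an estimated correlation; that for oxidative phosphorylation became 0.491 with the length trend removed.

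Some hypothalamic neuropeptide genes rose and some fell. Of 29, 6 rose, 2 fell and 21 did not pass (14 rose and 3 fell when adjusted over the list alone). The 6 included Tac1, which also stands in the thalamus list, and Penk, which also stands in the striatum list. Avp, the vasopressin precursor, rose from 241 ± 17.6 to 364 ± 8.05 CPM (SD, n = 3 each; log2 fold change 0.60 ± 0.06 SE, edgeR adjusted p = 0.00248), and Pdyn and Cartpt rose by 0.45 ± 0.08 and 0.32 ± 0.07. Hcrt, the orexin precursor, went from 191 ± 48.9 to 108 ± 5.75 CPM (edgeR adjusted p = 0.0161), and Npvf also fell. The list passed camera at an adjusted p of 0.00915, and adjusted p = 0.316 with an estimated correlation. Among 37 hormone and neuropeptide receptors, the melanocortin receptors Mc4r (1.06 ± 0.21) and Mc3r (0.64 ± 0.12) and the incretin receptor Gipr (0.71 ± 0.18; lost in 13 of 20 alternatives) rose and Igf1r fell (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.157). Among 30 hypothalamic transcription factors, Lhx6 (1.35 ± 0.17) and Rax (1.35 ± 0.32) rose and Pou3f2 and Tcf4 fell (3 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.913). That list's median log2 fold change was -0.02 and its mean 0.02. Among 16 tanycyte genes, Gpr50, Rax and Col23a1 rose and Cd59a fell (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0384, and adjusted p = 0.480 with an estimated correlation).

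Markers of neighbouring regions differed between libraries. Of 15 thalamus and habenula genes, Plekhg1 and Tcf7l2 fell and Tac1 rose (calls lost in 8, 14 and 7 of 20 alternatives; 1 rose and 6 fell when adjusted over the list alone), and of 15 cortex, hippocampus and amygdala genes, Cux2 and Neurod6 fell (5 when adjusted over the list alone). Camera adjusted p was 0.00935 and 0.00170, and adjusted p = 0.340 and 0.359 with an estimated correlation; both lists lost the preset call without young replicate 2. Slc17a7, a vesicular glutamate transporter of cortex and thalamus, did not pass (edgeR adjusted p = 0.0832) and stood at 173 CPM in young replicate 2, 58.5 in young replicate 3 and 11.2 in young replicate 1. Slc6a3 stood at 89.4 and 113 CPM in young replicates 2 and 3, against 22.6 in young replicate 1 and 4.27 to 19.2 in the aged libraries. It was the member that fell among 13 monoamine and acetylcholine genes (4 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.913). Among 16 striatal genes Penk rose (1 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.385).

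**Figure D3:**
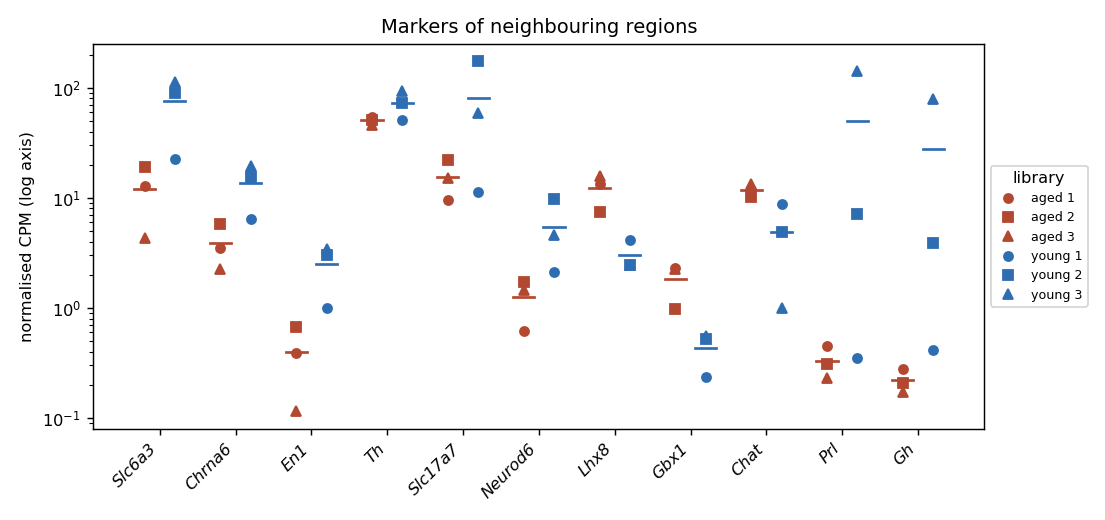
Levels of 11 genes, most chosen after their values were seen, that mark midbrain, cortex or thalamus, basal forebrain and pituitary, as normalised CPM on a log axis; symbols are libraries, and bars are group means. Prl and Gh reach 142 and 78.2 CPM in young replicate 3, and Slc6a3 113 CPM.

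In 8 marker lists no gene passed in edgeR: neurons (16 tested), ependymal cells (16), choroid plexus (10), red blood cells (8), perivascular macrophages (6), pituitary (6), T cells (3) and B and plasma cells (1). Of these 66 genes, 11 had an unadjusted p under 0.05, 2 passed in DESeq2, 0 in limma-voom, 5 in limma-voom with sample weights and 1 in limma-trend on FPKM. Adjusted over the list alone, Lhx3 rose and Pcsk2 fell in the pituitary list, and no gene passed in the others. Camera adjusted p was 0.234 for neurons, 0.671 for ependymal cells, 0.376 for choroid plexus, 0.387 for red blood cells, 0.833 for perivascular macrophages, 0.494 for pituitary and 0.131 for T cells; the B and plasma cell list was not tested. Without single libraries, red blood cells passed without aged replicate 3 (0.000896), T cells without aged replicate 1 (0.0208) and choroid plexus without young replicate 3 (0.0349).

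Of 49 lists tested, 30 passed camera with the preset correlation, 19 higher and 11 lower in aged. With an estimated correlation 0 passed, with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.121. Fry called 19 lists. It kept 15 of the 30 and lost 15, among them astrocytes, oligodendrocyte precursors, heat shock, glutamate, proteasome and neuropeptide genes. Its 19 also held GABA signalling, immature neuron, lysosome and antioxidant genes, which had not passed camera (fry adjusted p = 0.0484, 0.0430, 0.00966 and 0.0453). With the gene length trend removed 8 of the 30 lost the call, by ranks 6 and on log2(FPKM + 1) 4. Homeostatic microglia, neuropeptides and tanycytes lost it in all 3, and senescence and matrix genes by ranks and without the length trend. The clock list lost it by ranks and on log2(FPKM + 1), and oxidative phosphorylation and thalamus genes without the length trend. The other 9 divisions of the 6 libraries gave 4 to 32 lists with the preset correlation and 0 genes in edgeR. Each of these mixes aged and young libraries within its groups, which adds any difference between them to the spread. Their 0 genes are therefore no measure of chance.

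**Figure D4:**
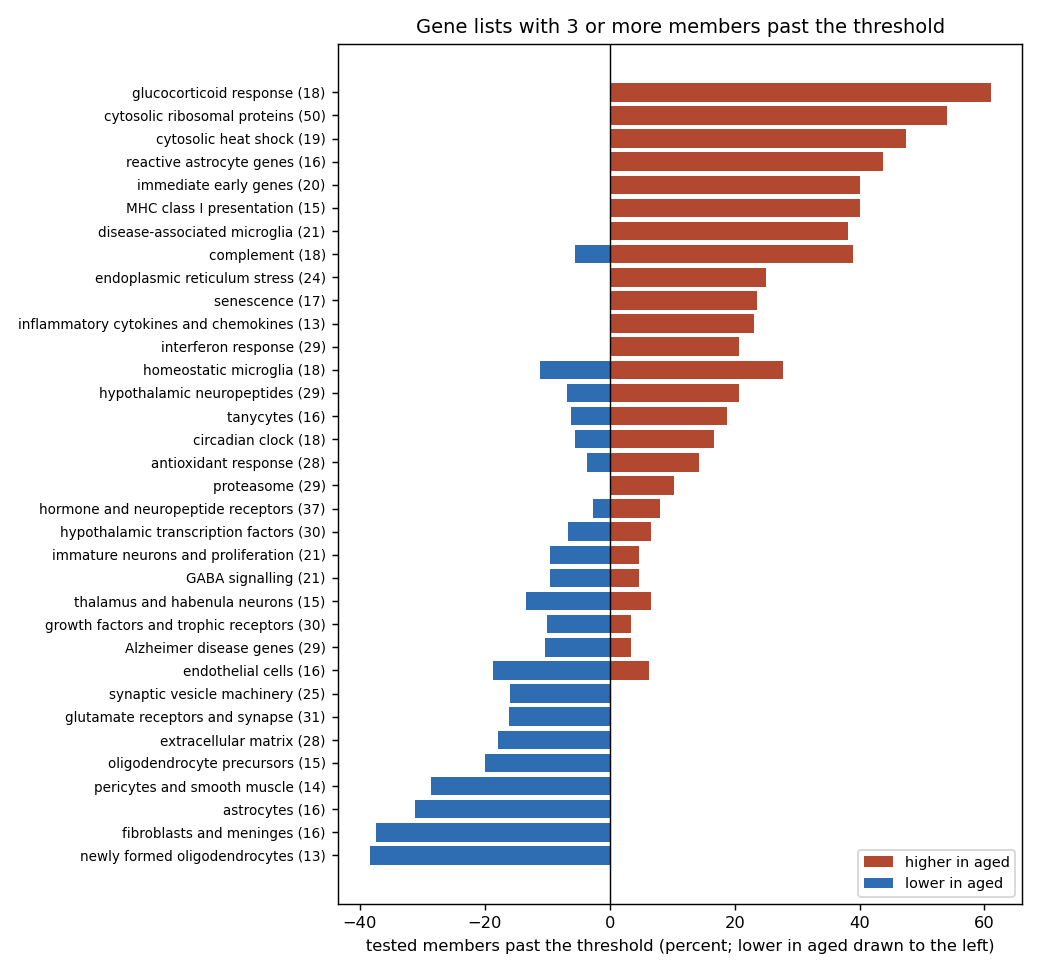
Share of tested members past the edgeR threshold for the 34 lists with 3 or more such members, in percent, with genes higher in aged to the right and lower in aged to the left; tested members are in brackets. Glucocorticoid response, with 11 of 18, stands at the top, and newly formed oligodendrocytes, with 5 of 13, at the bottom.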

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

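The tests of midbrain, pituitary and basal forebrain tissue were set before their results were seen, from marker lists written after the first look at the data. Of the genes left out by the low-count filter, 6 had at least 100 reads in a library. Prl and Gh, the prolactin and growth hormone genes of the pituitary, had 2561 and 1407 reads in young replicate 3, 125 and 67 in young replicate 2 and at most 8 in each other library. In aged replicate 2, Bpifa1 had 120, Il2rb 108 and Gimap3 101 reads. In aged replicate 3, Lcn2 had 150 reads.

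Markers of neighbouring regions differed between the libraries in both directions. Of 12 tested midbrain dopamine neuron markers other than Slc6a3 and Chrna6, 11 had log2 fold changes below 0 and 2 passed. Their median was -0.45 (bootstrap interval -0.64 to -0.34, over genes and not over mice). Young replicate 1 lay within the aged range for 6 of the 12, so this is consistent with more midbrain tissue in young replicates 2 and 3. Of 8 basal forebrain markers other than Lhx8, which was chosen after its values were seen, 7 had log2 fold changes above 0 and 1 passed, with a median of 0.99 (0.29 to 1.31), consistent with more basal forebrain tissue in the aged samples. Pituitary genes other than Prl and Gh summed to 5.73 CPM in young replicate 3, 0.886 times the mean of the other 5 libraries (2.81 to 9.34 CPM). Though under the bound of 1.5 set beforehand, this decides nothing, as 6 of the 10 genes were below the low-count filter and the sum rests largely on Cga (0 to 5.07 CPM), so pituitary tissue stays open. A change of midbrain or basal forebrain neurons with age or sex also stays open and was not tested.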

How the results depend on the processing

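No gene called in the main test changed direction under any of 20 alternatives run on all genes, and of 126 named genes that passed, 54 kept their call in each. Tcf7l2 lost it in 14, Grid2ip and Gipr in 13, Opalin in 11, Neurod6 and Icam1 in 10, and Tcf4, Slc6a3, P2ry12, H2-Ab1, Dcx, Col23a1 and Chrna6 in 9 of the 20. Genes higher or lower in aged numbered 1265 and 1303 with limma-voom and sample weights, 1017 and 1170 at adjusted p under 0.1, 298 and 122 on log2(FPKM + 1) without a filter, and 154 and 82 at unadjusted p under 0.05 and over 2-fold. Lower genes fell to 293 on log2(FPKM + 1), 303 on log2(FPKM + 0.1) and 346 with the length trend removed, which was added after the data were seen; the cause was not tested for the FPKM counts. Leaving out single libraries gave 95 to 901 higher and 55 to 732 lower genes, with fewer samples in each. Without X- and Y-linked genes, also added later, 446 were higher and 514 lower. Lists past the threshold numbered 0 with an estimated correlation, 19 with fry and 28 to 32 without single libraries. Of the 30, 15 lost the call with fry, 8 with the length trend removed, 6 by ranks and 4 on FPKM. Tanycytes, growth factors, homeostatic microglia, neuropeptides, clock, thalamus and cortex lists each lost it without at least 1 single library. Tanycytes also lost it with total counts alone. The replicate block gave 523 higher and 667 lower genes. Pair correlations were 0.10, 0.04 and -0.14, and 2 of 6 samples matched best with their own number. With 3 libraries per group, these values cannot decide whether the numbers pair the animals. Some lists that had not passed changed direction, and the cause was not tested: adjusted p was 0.716 for perivascular macrophages at 1 CPM; 0.947 for hypothalamic transcription factors and 0.958 for monoamine genes under the block; and 0.810 by ranks, 0.986 on FPKM and 0.915 without the length trend for Alzheimer disease genes. Without single libraries, adjusted p ran from 0.081 to 0.965 for myelinating oligodendrocytes, 0.229 to 0.972 for ependymal cells, 0.0349 (without young replicate 3, a pass) to 0.727 for choroid plexus, 0.135 to 0.965 for pituitary, 0.0802 to 0.625 for striatum, 0.574 to 0.965 for hypothalamic transcription factors, 0.480 to 0.972 for monoamine genes and 0.450 to 0.918 for Alzheimer disease genes. Cga, which had not passed, was at -0.17 with sample weights. The difference in mean depth, 299490 reads, ran from -159514 (without aged replicate 2) to 678542.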

Other observations

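The tests of sex, of exchanged libraries, of age rather than sex, of endothelial cells and of clock phase were chosen after the results were seen. Some genes linked to Alzheimer disease rose and some fell. Of 29, Trem2, a microglial receptor, rose by 0.47 ± 0.10, and Ide, the insulin-degrading enzyme, Sorl1 and Clu changed by -0.59 ± 0.07, -0.45 ± 0.05 and -0.26 ± 0.06 (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.641; the median was 0.03 and camera's direction was down). Of 28 antioxidant genes, Srxn1 (0.56 ± 0.11), Gpx1 and Gpx4 were among 4 that rose, and Cat, the catalase gene, changed by -0.61 ± 0.08 (6 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.157).

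Of 30 growth factors and trophic receptors, 1 rose and 3 fell: Ret, Igf2 and Igf1r changed by -0.76 ± 0.13, -0.56 ± 0.09 and -0.39 ± 0.07 (1 rose and 4 fell when adjusted over the list alone). Ret is also among the 2 midbrain markers that passed. It stood at 66.3 CPM in young replicate 1, 88.8 and 89.4 in young replicates 2 and 3, and 41.5 to 54.5 in the aged libraries. The camera adjusted p of the growth factor list was 0.0260, and adjusted p = 0.295 with an estimated correlation and 0.121 with the length trend removed. Of 21 genes of immature neurons and proliferation, Nes rose and 2 fell, among them Dcx (2 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.119). Ctsz and Ctsd rose among 34 lysosome and autophagy genes (4 when adjusted over the list alone; camera adjusted p = 0.0811), and Pmvk among 23 cholesterol synthesis genes (1 when adjusted over the list alone; camera adjusted p = 0.178).

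The summed Y-linked level in the highest young library was 1.02% of that in the lowest aged library, and the median log2 fold change of 7 X-linked genes that escape inactivation was -0.41; both suggest that the aged mice were male and the young mice female. Over autosomal genes, the lowest correlation within a group (0.990) lay above the highest between groups (0.989). On average, 0 libraries were closer to the other group. As the groups also differ in Y-linked expression, these correlations may follow sex rather than age. They therefore do not decide whether 1 or 2 libraries were exchanged between the ages. X-linked genes made up 3.93% of the lower genes (exact binomial interval 2.45% to 5.94%), against 3.60% of tested genes. Most lower genes were therefore not X-linked themselves. An effect of X-linked genes on autosomal genes was not tested and stays open. As 0 libraries break the coincidence, age and sex cannot be told apart for the called autosomal genes.

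The 28 called glucocorticoid, heat shock and early response genes had a median log2 fold change of 1.25, and of 1.07 at the lowest without an aged library. As these genes were chosen by passing with all libraries, that does not decide whether 1 library was the whole cause; 20, 27 and 18 still passed without aged replicates 1, 2 and 3. The endothelial list had a median of -0.12 (bootstrap interval over its genes -0.36 to 0.07), so endothelial markers as a set were not higher. Marker RNA may also change within cells, so this does not decide whether the aged samples held more endothelial cells. Clock genes other than Per1 and Per2 had a median absolute change of 0.24 (0.11 to 0.30), with 1 that rose and 1 that fell; as the change a shifted phase would bring to each is not known, a shifted phase stays open. A stress response around death or handling that differed between groups, in the order of dissection for example, may remain, as may an effect of age or sex; none was tested.

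Among the 10 divisions of the 6 libraries, counting the real one, 1 gave at least 1009 called genes (the highest other gave 0). Counting it too, 2 gave at least 30 lists (the highest other gave 32). Each other division mixes aged and young libraries within its groups, so any difference between the ages or sexes adds to the spread there. The 0 genes of the other divisions are therefore no measure of chance. With 10 divisions no share under 0.05 can be reached.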
